A study of Mus musculus with 18 samples.

How the data were processed

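Gene expression was measured in mouse bone marrow-derived dendritic cells on 18 Affymetrix Mouse Gene ST arrays. Per the labels, marrow cells were grown for 10 days in medium with 10% fetal bovine serum and 20 ng/ml of the cytokine GM-CSF, and 100 nM 4-hydroxytamoxifen was given on day 6. The cells were wild type or knockout for Ubc9, the enzyme that joins the small protein SUMO to other proteins. They were left without stimulation or received 10 ng/ml of bacterial lipopolysaccharide (LPS) for 1 h or 6 h. The 2 genotypes and 3 conditions make 6 groups with 3 arrays each, which the series design calls biological replicates. Each array took 200 ng of total RNA.

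The deposited table holds log2 signal values that the authors made with RMA (background correction, quantile normalization and summary per transcript cluster). The labels name no software version, and the log base is not stated: the highest value is 13.71, which is in the range of RMA log2 signals and far below linear intensities. The values were used as deposited. The values carry no detection calls, so the size of a change against a group with low signal is less certain than its error shows. With arrays, the spread between the 3 replicates of a group sets the precision.

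The table has 35556 probe sets. An annotation table for the platform names 1 gene symbol for 21789 of them and several symbols for 1621, and does not list 12146. For 21698 of the probe sets with 1 symbol, the symbol was matched through its gene identifier to a gene table of the mouse assembly GRCm38.p6, used here for names only, and 0 symbols needed an update. Where several probe sets named a gene (999 genes), the one with the highest mean over all 18 arrays was kept, which left 19938 genes. Genomic positions are not given in the sources used here.

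The comparisons below with their tests, the gene lists and the naming rule were fixed before the data were examined. The closing section names the tests of explanations that were chosen later. All 18 arrays entered 1 fit of 6 group means in limma 3.58.1 (R 4.3.3), with 12 residual degrees of freedom and moderated variances. Contrasts from this fit gave 9 comparisons: knockout minus wild type in each of the 3 conditions, each LPS time minus unstimulated in each genotype, and the difference between the genotypes' LPS responses (interaction) at 1 h and at 6 h. Tests were 2-sided, and p values were adjusted by the Benjamini-Hochberg method over all 19938 genes. A gene was called at an adjusted p under 0.05, and a 2-fold change means an absolute log2 fold change of at least 1. Errors of log2 fold changes are standard errors from this fit, with 3 arrays in each group.

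The text names genes by a rule. For each knockout minus wild type comparison and each interaction it takes the 10 largest rises and the 10 largest falls among called genes. In the genotype comparisons the 3 values of each group had to lie apart, which chance gives for 10% of genes with 3 against 3. LPS responses of wild-type cells use 10 rises and 5 falls. Predicted or unnamed genes (2892) are counted but not named. From each list, up to 4 called members with the smallest adjusted p are added, or up to 2 with the largest change where none was called, and a gene named in 1 comparison may be followed into the others.

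The 27 lists hold 508 entries, of which 467 were measured, 5 of them under another symbol. They cover SUMO machinery, immediate-early genes, inflammatory cytokines and mediators, chemokines, type I interferon production and signalling, interferon-inducible antiviral genes, NF-kB subunits and feedback inhibitors, Toll-like receptor signalling, dendritic cell maturation, MHC and antigen presentation, cell cycle, p53 targets, the integrated stress and unfolded protein response, heat shock proteins, sterol synthesis, LXR and PPARG targets, glycolysis and itaconate, and germline genes. The marker lists cover conventional and plasmacytoid dendritic cells, macrophages, neutrophils and granules, B cells, T and NK cells, mast cells and basophils, erythroid cells and stromal cells. Each list was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated per list. Counts of called list members are given over all genes and adjusted over the list alone.

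Whether the replicate numbers pair arrays was checked on values centred on their group means. Within a genotype, all 18 pairs of arrays with the same number and different conditions correlated positively (r from 0.15 to 0.80 across genes), and all 18 arrays correlated best with an array of their own number. The numbers therefore pair the arrays within a genotype, and the replicate block within genotype (6 fixed blocks) called 3002 genes for the 6 h response of wild-type cells, against 1614 without it. Its values stand beside the counts of genes and list members given for the LPS responses and interactions where they differ by over 1.5 times. Across genotypes, numbers were taken to pair the arrays of a comparison where all 3 pairs correlated above 0.1. Pairs with the same number and condition correlated at 0.02 to 0.08 without LPS and at 0.10 to 0.15 at 1 h, so these arrays were not treated as paired. At 6 h they correlated at 0.11 to 0.17, so the numbers pair these arrays by this rule. A replicate block called 6560 genes there, against 5863 without it. This block gives each number the same effect on all 18 arrays of both genotypes. It thus also joins arrays that were not treated as paired. Values with this block at 6 h are therefore given as an alternative, not as a fit of the 6 h pairs alone. Pairs across genotypes and conditions with the same number correlated at −0.11 to 0.30. All of this pairing comes from the data, not from the labels.

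Alternatives were a replicate block, a random replicate block, variances with a trend and robust moderation, array weights, only the groups compared, dim genes (below the 30th percentile) left out, all probe sets tested, quantile normalization repeated, arrays centred on their medians, and each array left out in turn. A fit without the 3 knockout arrays numbered 3, and camera with blocks within genotype, were added after seeing the data. The closing section gives their effects.

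The scripts were tested on simulated data with the size and grouping of the real table. Of genes given a simulated log2 change of 1, the fit recovered 92.5% in the unstimulated genotype comparison and 65.7% in the interaction at 1 h, and in these comparisons it called 6 and 8 unchanged genes. A list shifted as a whole was recovered. The simulated noise was independent between genes and between arrays. These tests therefore do not show how the fit or camera behaves with correlated genes or paired arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.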

Results

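RNA was measured in dendritic cells grown from mouse bone marrow, which present antigens and respond to microbial products. Cells with and without Ubc9, the SUMO-conjugating enzyme, were compared unstimulated and after 1 h or 6 h of LPS, which is sensed through the receptor Tlr4. Each of the 6 groups held 3 arrays. Arrays of the same group correlated at 0.983 to 0.993 (Pearson's r across probe sets, which are not independent replicates). The first principal component of the gene levels held 51.3% of the variance. The knockout arrays at 6 h lay between 54.7 and 78.1 on it, and all other arrays between −36.1 and 21.8. In each condition, knockout array 3 lay highest of the knockout arrays on this component, at 17.6 unstimulated, 21.8 at 1 h and 78.1 at 6 h. The 75th percentile of signal was 7.15 to 7.33 on the knockout arrays at 6 h and 7.45 to 7.46 on the wild-type arrays at 6 h. The array means of the germline list were 3.53 to 3.77. Changes of genes with a group mean not far above that are uncertain in size, such as Ifnb1 (3.65 in unstimulated wild-type cells), Il6 (3.96 in unstimulated knockout cells), Tnfsf10 (4.14 in wild-type cells at 6 h) and Ifit3 (4.44), Nos2 (4.57) and Ifit1 (4.61) in unstimulated wild-type cells.

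The wild-type arrays show the LPS response of cells that have Ubc9. After 1 h, these cells had raised mRNAs of secreted inflammatory proteins and of the NF-kB pathway. Cxcl2, a chemokine that attracts neutrophils, rose by 4.72 ± 0.30 log2 units (SE, n = 3 per group, adjusted p = 5.5e-07), and the cytokine Il1b by 3.79 ± 0.35. Of 26 inflammatory cytokines and mediators, 7 rose, 0 fell and 19 were not called (10 adjusted over the list alone), with Tnf at 2.98 ± 0.21 and Il1a at 2.27 ± 0.17 (camera adjusted p = 1.4e-20). Of 18 NF-kB subunits and feedback inhibitors, 8 rose and 0 fell (14 adjusted over the list alone; camera adjusted p = 5.3e-35). Among them were Nfkbiz (3.45 ± 0.23), Nfkbia (1.77 ± 0.17) and Tnfaip3 (2.36 ± 0.21), which encode regulators of NF-kB. Of 24 immediate-early genes, 3 rose (12 adjusted over the list alone, 7 with the replicate block within genotype), among them the transcription factor Junb by 1.20 ± 0.10 (camera adjusted p = 5.2e-16). Of 19 chemokines, 4 rose (4 adjusted over the list alone), but 2 without array 2 or 3 at 1 h or without unstimulated array 1. The chemokine list's camera result was adjusted p = 2.5e-09, and adjusted p = 0.13 with an estimated correlation. Interferon-inducible antiviral genes had a median of −0.06 (camera adjusted p = 0.54). In limma, 60 of 19938 genes were called, 51 higher and 9 lower, and 38 rose at least 2-fold. The count was 133 with the replicate block within genotype, with only these groups 31, without array 3 at 1 h 28, and without array 2 at 1 h 34.

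By 6 h, wild-type cells had also raised interferon-inducible genes. Of the 35 measured, 30 rose, 0 fell and 5 were not called (33 adjusted over the list alone), with a median of 1.99. Ifit3, which encodes an antiviral protein, rose by 4.77 ± 0.43 log2 units (SE, n = 3 per group, adjusted p = 3.6e-06), from a low mean of 4.44. The list's camera result was adjusted p = 8.9e-36, and adjusted p = 0.082 with an estimated correlation. Irf7, a transcription factor of interferon genes, rose by 2.69 ± 0.39, and Ifnb1, which encodes interferon beta, stood at 0.83 ± 0.40 (adjusted p = 0.28; 0.018 with only these groups). Of the inflammatory cytokines and mediators, 13 rose and 0 fell (15 adjusted over the list alone; camera adjusted p = 1.5e-15). Il6 rose by 4.79 ± 0.50 and Ptgs2, the inducible prostaglandin synthase, by 4.20 ± 0.30. Of the NF-kB list, 15 of 18 rose (15 adjusted over the list alone; camera adjusted p = 9.6e-26). Of the chemokines, 12 rose (13 adjusted over the list alone; 7 without array 2 at 6 h), with Cxcl3 at 5.97 ± 0.47 and Cxcl10 at 5.61 ± 0.58. That list's camera result was adjusted p = 7.6e-12, and adjusted p = 0.063 with an estimated correlation. Of 16 genes of dendritic cell maturation, 6 rose (7 adjusted over the list alone, 13 with the replicate block within genotype). They included the co-stimulatory receptor Cd40 (2.90 ± 0.30) and the adhesion molecule Icam1 (1.54 ± 0.14). Camera gave adjusted p = 8.9e-11 for this list, and adjusted p = 0.063 with an estimated correlation. LXR and PPARG targets, genes of lipid handling, included 1 rise and 4 falls among 17 (6 adjusted over the list alone; 1 rise and 7 falls with the replicate block within genotype), with the cholesterol exporter Abcg1 at −1.30 ± 0.12 and Cpt1a, of fatty acid import into mitochondria, at −1.10 ± 0.08. Their camera result was adjusted p = 5.9e-04, and adjusted p = 0.082 with an estimated correlation. The largest named falls were in the organic anion transporter Slco2b1 (−2.21 ± 0.42) and the retinaldehyde reductase Dhrs3 (−2.03 ± 0.18). In limma, 1614 genes were called, 844 higher and 770 lower. With the replicate block within genotype 3002 genes were called, without array 2 at 6 h 901, and without array 3 at 6 h 986.

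Without LPS, the genotypes differed in genes of the interferon response and of sterol synthesis. Interferon-inducible antiviral genes were far higher in knockout cells: 31 of 35 were called higher, 0 lower and 4 not called (35 adjusted over the list alone), with a median of 2.83 log2 units. Ifit3 averaged 11.14 ± 0.58 (SD, n = 3) in knockout and 4.44 ± 0.61 in wild-type cells, a difference of 6.70 ± 0.43 (SE, adjusted p = 1.5e-07; uncertain in size, as the wild-type mean is low). The antiviral genes Rtp4 (5.34 ± 0.33), Rsad2 (4.59 ± 0.55) and Oas3 (3.94 ± 0.31) were also higher. The list's camera result was adjusted p = 1.0e-75, and adjusted p = 0.048 with an estimated correlation. Of 18 genes of type I interferon production and signalling, 5 were higher and 0 lower (7 adjusted over the list alone), among them the transcription factors Irf7 (5.09 ± 0.39), Irf9 (1.38 ± 0.14) and Stat2 (1.96 ± 0.33). The list's count was 3 without knockout array 2 or 3 or wild-type array 3, and its camera result was adjusted p = 6.7e-05, and adjusted p = 0.38 with an estimated correlation. Ifnb1 was higher by 1.81 ± 0.40 (adjusted p = 0.021), against a wild-type mean of 3.65, near the array means of the germline list (3.53 to 3.77). This call was lost without knockout array 2 (adjusted p = 0.068) or 3 (0.089), without wild-type array 2 (0.064) or 3 (0.079), and with only these groups (0.21). Of 19 chemokines, 4 were higher and 1 lower (9 adjusted over the list alone), including Cxcl10 (4.43 ± 0.58) and Ccl4 (1.58 ± 0.28), and 8 were called without knockout array 1. In camera the result was adjusted p = 4.7e-04 for chemokines, and adjusted p = 0.38 with an estimated correlation. The antigen peptide transporter Tap1 was higher by 1.92 ± 0.27, 1 of 6 among 15 genes of MHC and antigen presentation that were higher (9 called adjusted over the list alone; 3 without knockout array 3; camera adjusted p = 0.086). As for markers of other cells, 2 of 14 macrophage markers were higher, Adgre1 by 0.71 ± 0.14 and Fcgr1 by 3.09 ± 0.72. Without knockout array 3 or wild-type array 2 neither was called (Adgre1 adjusted p = 0.074 and 0.068, Fcgr1 0.16 and 0.076). Fcgr1 was also lost without knockout array 2 (0.086), wild-type array 1 (0.12) or wild-type array 3 (0.0504). The macrophage list's means were 8.56, 8.85 and 9.6 on knockout arrays 1, 2 and 3, and 8.34, 8.51 and 8.6 on the wild-type arrays. Whether the mix of cells differed between the genotypes was not tested.

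Genes of sterol synthesis were lower in unstimulated knockout cells. Of 17 measured, 0 were higher, 5 lower and 12 not called, and all 17 were called lower when adjusted over the list alone, with a median of −0.87 log2 units. Mvd, an enzyme of the mevalonate pathway, stood at −1.15 ± 0.13 (SE, n = 3 per group, adjusted p = 6.5e-05). The list's camera result was adjusted p = 2.6e-18, and adjusted p = 0.28 with an estimated correlation. The count over all genes was 1 without knockout array 2 or 3 or wild-type array 3, and 2 without wild-type array 2. It was 8 without knockout array 1 and 11 without knockout array 1 at 6 h. The lipid genes Fabp4, a fatty acid carrier (−1.60 ± 0.19), and Scd2, a fatty acid desaturase (−1.36 ± 0.24), were lower too. They were among 3 of 17 LXR and PPARG targets that were lower (6 called adjusted over the list alone; camera adjusted p = 0.053). The largest fall of a named gene was in the zinc finger gene Zfp518a (−1.80 ± 0.11). The lists of NF-kB genes (median 0.03, camera adjusted p = 0.83) and dendritic cell maturation (median −0.04, adjusted p = 0.74) were not called. Of 26 inflammatory cytokines and mediators 1 was higher and 0 lower (3 adjusted over the list alone), with a median of 0.19, and of 21 genes of Toll-like receptor signalling 2 were higher and 0 lower (6 adjusted over the list alone), with a median of 0.22. Both lists were called by camera (adjusted p = 0.0025 and 0.0021), and both had adjusted p = 0.38 with an estimated correlation. The inflammatory count was 4 without knockout array 1, and 0 without knockout array 2 or 3 or wild-type array 1 or 2. The Toll-like receptor count was 0 without knockout array 2, and 1 without knockout array 3 or wild-type array 1 or 2. The cell cycle list was called lower by camera, but not with an estimated correlation (values in the closing section). Its means on knockout arrays 1, 2 and 3 were 8.25, 7.89 and 6.75, and on the wild-type arrays 7.99, 8.18 and 7.92. In limma, 487 genes were called, 359 higher and 128 lower, and 179 of them at least 2-fold higher. With only these groups 153 genes were called, without knockout array 3 there were 274, and without wild-type array 2 there were 281.

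**Figure D1:**
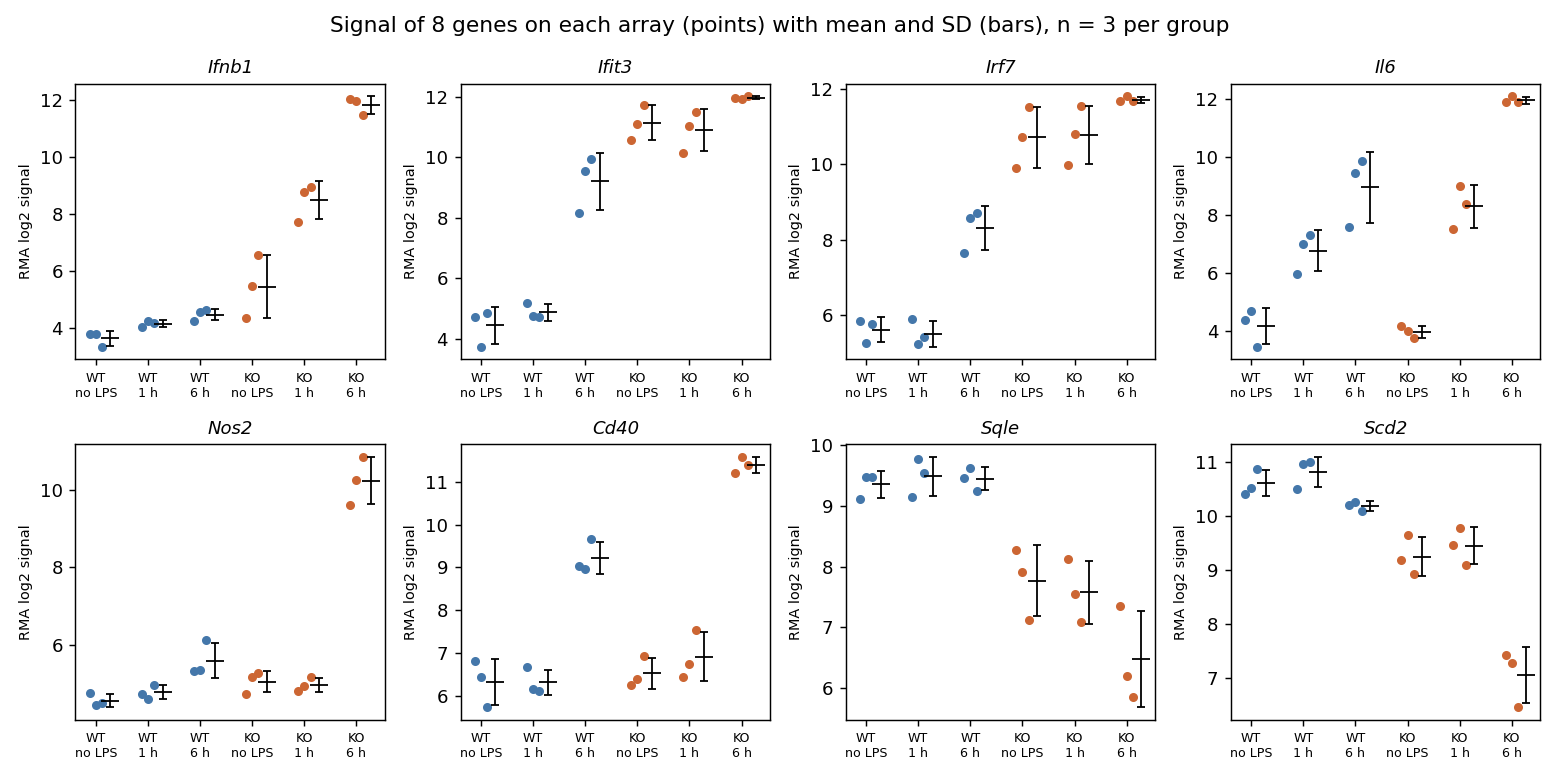
RMA log2 signal (vertical axes) of 8 genes on each of the 18 arrays by genotype and condition (points, 3 per group), with group means and SD (bars). Ifnb1 averaged 3.65, 4.16 and 4.48 in wild-type cells unstimulated, at 1 h and at 6 h, and 5.46, 8.49 and 11.83 in knockout cells.

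After 1 h of LPS, knockout cells had higher levels of interferon-inducible, early-response and chemokine genes and lower levels of sterol synthesis genes. Interferon beta (Ifnb1) was higher in knockout cells by 4.33 ± 0.40 log2 units (SE, n = 3 per group, adjusted p = 8.1e-06), against a wild-type mean of 4.16. Of the interferon-inducible antiviral genes, 31 of 35 were higher and 0 lower (35 adjusted over the list alone), with a median of 2.77, including Oasl2 (4.45 ± 0.40) and Ifitm3 (3.21 ± 0.26). Camera gave adjusted p = 2.3e-90 for this list, and adjusted p = 0.012 with an estimated correlation. Of 24 immediate-early genes, 5 were higher and 0 lower (10 adjusted over the list alone), among them Ier3 (1.00 ± 0.12), Junb (0.65 ± 0.10) and Egr1 (1.19 ± 0.21). Their count was 3 without wild-type array 1 or 2, and camera gave adjusted p = 7.0e-07, and adjusted p = 0.012 with an estimated correlation. Of 19 chemokines, 7 were higher and 1 lower (9 adjusted over the list alone; 5 called without knockout array 3), including Ccl7 (3.68 ± 0.64) and Cxcl1 (2.01 ± 0.34). In camera the result was adjusted p = 4.8e-08 for chemokines, and adjusted p = 0.097 with an estimated correlation. Of the inflammatory cytokines and mediators, 3 of 26 were higher (8 adjusted over the list alone; 1 without array 2 of either genotype), among them Ptgs2 by 2.22 ± 0.30. Their camera result was adjusted p = 5.5e-09, and adjusted p = 0.082 with an estimated correlation. Of the sterol synthesis genes, 10 of 17 were lower and 0 higher (17 adjusted over the list alone), with a median of −1.05, among them Sqle, the enzyme of squalene oxidation, by −1.91 ± 0.35. Without knockout array 2 or 3 the count was 4 or 3, and without wild-type array 1, 2 or 3 it was 6, 3 or 4. The sterol list's camera result was adjusted p = 5.7e-22, and adjusted p = 0.087 with an estimated correlation. The macrophage markers Fcgr1 (3.02 ± 0.72, adjusted p = 0.037) and Marco (−2.64 ± 0.60, adjusted p = 0.026) went in opposite directions. Neither was called without knockout array 2 or 3 or wild-type array 1 or 2 (Fcgr1 adjusted p = 0.11, 0.19, 0.17 and 0.12; Marco 0.087, 0.14, 0.15 and 0.11). Fcgr1 was also lost without wild-type array 3 (0.056), array 2 of unstimulated knockout cells (0.053), or array 2 at 6 h of knockout (0.052) or wild-type cells (0.052). In limma, 436 genes were called, 299 higher and 137 lower. With only these groups 257 genes were called, and with array weights 929. Without knockout array 3 or wild-type array 2 there were 243 genes, and without wild-type array 1 there were 269.

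Further lists were called higher by camera in knockout cells at 1 h of LPS. Of 18 NF-kB genes 1 was higher and 0 lower (3 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 1.7e-09, and adjusted p = 0.097 with an estimated correlation). That count was 0 without knockout array 2 or 3 or wild-type array 1, and 2 without knockout array 1, wild-type array 3 or unstimulated knockout array 1 or 3. Of 15 genes of MHC and antigen presentation 5 were higher and 0 lower (6 adjusted over the list alone), with a median of 0.11 and Tap1 at 1.90 ± 0.27 log2 units (SE, n = 3 per group; camera adjusted p = 0.0015, and adjusted p = 0.25 with an estimated correlation). The MHC count was 2 without knockout array 3, and 1 or 3 without wild-type array 2 or 3. Type I interferon production and signalling had a median of 0.18 (camera adjusted p = 1.9e-08, and adjusted p = 0.097 with an estimated correlation). Toll-like receptor signalling had a median of 0.16 (camera adjusted p = 4.3e-04, and adjusted p = 0.099 with an estimated correlation). Of 20 genes of the SUMO machinery 2 were higher and 0 lower (4 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 4.3e-04, and adjusted p = 0.097 with an estimated correlation). LXR and PPARG targets were called lower, with a median of −0.13 (camera adjusted p = 0.040, and adjusted p = 0.27 with an estimated correlation).

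After 6 h of LPS the genotypes differed most widely. Ifnb1 was higher in knockout cells by 7.35 ± 0.40 log2 units (SE, n = 3 per group, adjusted p = 1.1e-08), and the death ligand Tnfsf10 by 6.13 ± 0.65. The wild-type mean of Ifnb1 was 4.48, close to the germline list's array means (3.53 to 3.77), so the size of its difference is uncertain. Of 26 inflammatory cytokines and mediators, 21 were higher, 0 lower and 5 not called (21 adjusted over the list alone), with a median of 0.94. Nos2, the inducible nitric oxide synthase, was higher by 4.63 ± 0.26, the cytokine Il27 by 3.48 ± 0.25 and Il6 by 3.01 ± 0.50. The list's camera result was adjusted p = 4.7e-11, and adjusted p = 0.12 with an estimated correlation. All 35 interferon-inducible antiviral genes were higher, with a median of 2.37, including Iigp1 (5.77 ± 0.77) and Oas3 (3.61 ± 0.31). Camera gave adjusted p = 1.9e-22 for this list, and adjusted p = 0.47 with an estimated correlation. Of 19 chemokines, 9 were higher and 0 lower (9 adjusted over the list alone), including Ccl12 (5.63 ± 0.86) and Ccl7 (5.30 ± 0.64). Their camera result was adjusted p = 5.4e-04, and adjusted p = 0.47 with an estimated correlation. Of 18 NF-kB subunits and feedback inhibitors, 8 were higher (9 adjusted over the list alone; 5 without wild-type array 1), among them Nfkbiz by 1.85 ± 0.23 and the cytokine signalling inhibitor Socs1 by 2.11 ± 0.22. That list gave adjusted p = 0.0042 in camera, and adjusted p = 0.47 with an estimated correlation. Of 16 genes of dendritic cell maturation, 5 were higher (6 adjusted over the list alone; 3 without wild-type array 2 or 3), including Cd40 (2.17 ± 0.30). In camera the result was adjusted p = 0.047 for it, and adjusted p = 0.47 with an estimated correlation. Of 21 genes of Toll-like receptor signalling, 8 were higher and 1 lower (10 adjusted over the list alone), with the RNA sensor Tlr3 at 2.90 ± 0.24 and the kinase gene Irak1 at −0.75 ± 0.11. Camera gave adjusted p = 0.024 for it, and adjusted p = 0.47 with an estimated correlation. Of 15 genes of MHC and antigen presentation, 7 were higher and 2 lower (11 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.47 with an estimated correlation).

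At 6 h of LPS, genes of sterol synthesis and the cell cycle were lower in knockout cells. Of 17 sterol synthesis genes, 16 were lower and 0 higher (17 adjusted over the list alone), with a median of −1.65, Sqle at −2.98 ± 0.35 log2 units (SE, n = 3 per group, adjusted p = 1.1e-05) and Lss, lanosterol synthase, at −1.94 ± 0.19. The list's camera result was adjusted p = 2.3e-11, and adjusted p = 0.47 with an estimated correlation. Scd2 was the named gene with the largest fall, at −3.14 ± 0.24, and Pparg, a lipid-sensing nuclear receptor, stood at −2.09 ± 0.21. Both are on the list of 17 LXR and PPARG targets, of which 4 were higher and 7 lower (11 adjusted over the list alone; camera adjusted p = 0.25). Of 29 cell cycle genes, 11 were lower and 0 higher (15 adjusted over the list alone; 19 lower with the replicate block), with a median of −0.77, including the mitotic genes Cdc20 (−1.44 ± 0.34) and Bub1b (−2.32 ± 0.57). Without 1 array at 6 h the cell cycle count was 17, 4 or 3 (knockout arrays 1, 2 and 3) and 4, 4 or 7 (wild-type arrays 1, 2 and 3). In camera the result was adjusted p = 7.5e-04 for the cell cycle, and adjusted p = 0.49 with an estimated correlation. Of 14 macrophage markers 3 were higher and 2 lower (6 adjusted over the list alone; 6 and 3 with the replicate block; 3 called in all without wild-type array 2 or 3), with Fcgr1 at 4.68 ± 0.72 and the scavenger receptor Marco at −2.76 ± 0.60 (camera adjusted p = 0.27). Of 8 plasmacytoid dendritic cell markers 3 were higher (3 adjusted over the list alone; 1 without wild-type array 1), led by the transcription factor Tcf4 at 2.43 ± 0.17. Their camera result was adjusted p = 0.028, and adjusted p = 0.47 with an estimated correlation. Itgax, which encodes the dendritic cell integrin CD11c, stood at −0.44 ± 0.08. In limma, 5863 genes were called, 2116 higher and 3747 lower, with 535 and 546 of them at least 2-fold. With arrays centred on their medians 1666 were higher and 3985 lower. The counts were 2154 and 2898 with quantile normalization repeated, and 3213 and 4459 with array weights. With genes in 5 equal groups from low to high mean signal, the median changes were 0.105, 0.148, 0.068, −0.304 and −0.194.

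**Figure D2:**
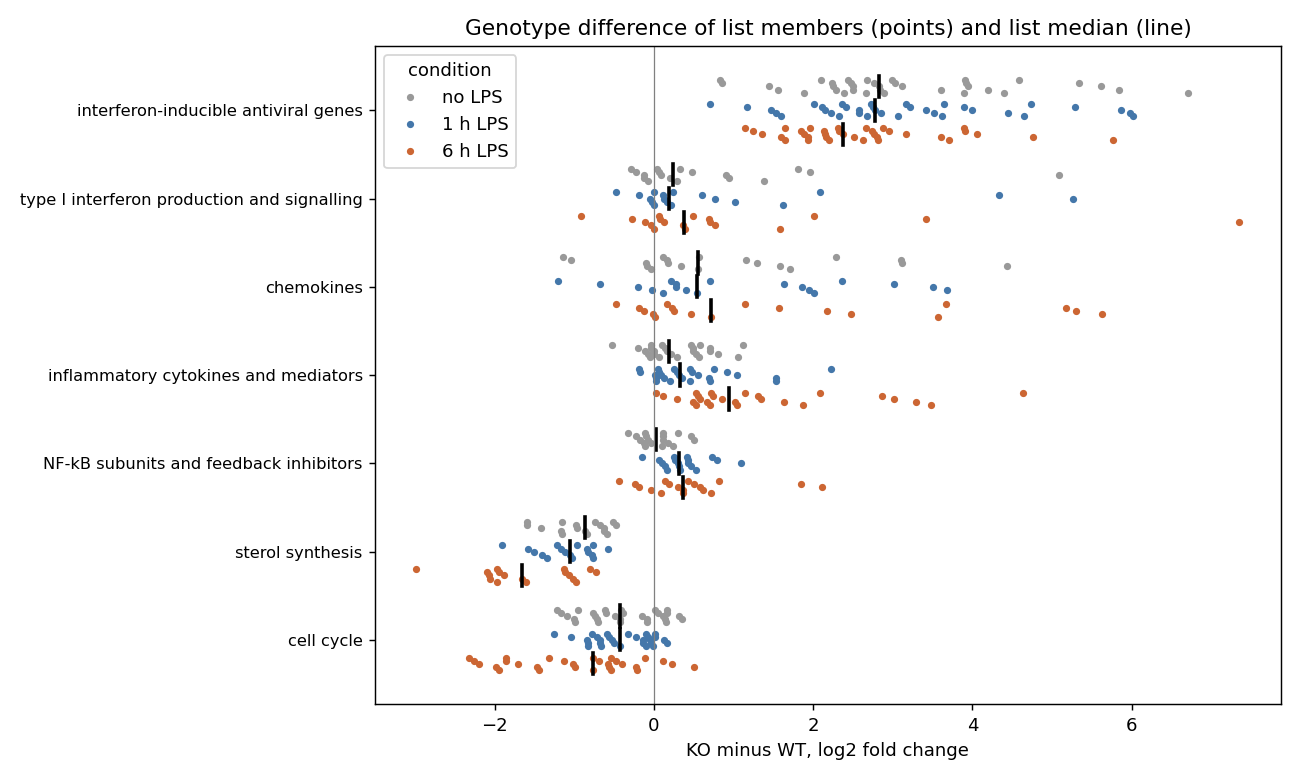
Knockout minus wild type log2 fold change (horizontal axis) of the members of 7 gene lists (points) in 3 conditions, with list medians (black lines). The interferon-inducible list's medians were 2.83, 2.77 and 2.37 unstimulated, at 1 h and at 6 h, and those of sterol synthesis −0.87, −1.05 and −1.65.

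Knockout cells responded to LPS with cytokine, NF-kB and maturation genes. At 1 h, Ifnb1 rose by 3.03 ± 0.40 log2 units (SE, n = 3 per group, adjusted p = 5.0e-04; 0.17 with only these groups), and Ptgs2 by 3.76 ± 0.30. Of 24 immediate-early genes, 12 rose and 0 fell (15 adjusted over the list alone), including Fosb at 2.27 ± 0.22 (0.063 with only these groups) and Junb at 1.47 ± 0.10 (camera adjusted p = 1.0e-36). Of 18 NF-kB genes 12 rose (16 adjusted over the list alone; camera adjusted p = 2.3e-51), and of 26 inflammatory cytokines and mediators 9 rose (12 adjusted over the list alone; camera adjusted p = 2.8e-26). By 6 h, 22 of these 26 had risen and 0 fallen (22 adjusted over the list alone), with Il6 at 8.01 ± 0.50 and Nos2 at 5.17 ± 0.26 (camera adjusted p = 8.2e-18). Of 19 chemokines 15 rose (15 adjusted over the list alone), and of 16 maturation genes 13 rose (14 adjusted over the list alone), including Cd40 by 4.87 ± 0.30. Camera gave adjusted p = 6.4e-10 for chemokines and 6.3e-09 for maturation, and adjusted p = 0.11 for both with an estimated correlation. Of the 35 interferon-inducible genes, 27 rose and 0 fell (30 adjusted over the list alone; camera adjusted p = 6.3e-12, and adjusted p = 0.41 with an estimated correlation). Of 17 sterol synthesis genes 10 fell and 0 rose (11 adjusted over the list alone), with a median of −0.66. Their count was 16 lower and 1 higher with the replicate block within genotype. It was 3 or 6 without unstimulated array 1 or 2, and 6 or 4 without array 2 or 3 at 6 h. In camera the result was adjusted p = 9.3e-04 for that list, and adjusted p = 0.50 with an estimated correlation. In limma, 133 genes were called at 1 h, 107 higher and 26 lower. With the replicate block within genotype there were 309, with only these groups 46, with array weights 281, without array 2 at 1 h 78, and without unstimulated array 1 there were 87. At 6 h, 6417 genes were called, 37.4% of them higher, or 26.5% with arrays centred on their medians, 42.3% with quantile normalization repeated and 43.2% with array weights. Among genes changed at least 2-fold, 36 rose at 1 h in both genotypes (38 in wild-type and 61 in knockout cells, 0.1 shared by chance). At 6 h, 196 rose in both (265 and 579, 7.7 by chance) and 67 fell in both (94 and 707, 3.3 by chance). Across genes, which are not independent, the genotypes' responses correlated at r = 0.61 (Spearman's rho = 0.39) at 6 h and at r = 0.56 (rho = 0.30) at 1 h.

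The interaction tests whether the LPS response itself differed between the genotypes. At 6 h it was larger in knockout cells for Ifnb1 by 5.54 ± 0.56 log2 units (SE, n = 3 per group, adjusted p = 3.2e-05; uncertain in size, as its wild-type means of 3.65 and 4.48 are low), for Nos2 by 4.14 ± 0.37, for Il27 by 3.31 ± 0.35 and for Il6 by 3.22 ± 0.71. Of 26 inflammatory cytokines and mediators, 9 had a larger and 0 a smaller response (14 adjusted over the list alone, 17 with the replicate block within genotype), with a median of 0.77. Camera gave adjusted p = 1.7e-07 for that list, and adjusted p = 0.34 with an estimated correlation. The response was smaller in knockout cells for 4 of 35 interferon-inducible genes and larger for 0 (6 adjusted over the list alone; camera adjusted p = 0.084). These were Ifit3 (−3.94 ± 0.60, from a low wild-type mean of 4.44), Rtp4 (−3.74 ± 0.47), Ifit1 (−3.47 ± 0.64) and Ifit2 (−2.67 ± 0.73), whose unstimulated levels in knockout cells, 10.45 to 11.14, were above the wild-type levels at 6 h, 9.12 to 9.79. With the replicate block within genotype, 7 were smaller and 2 larger. Leaving out any 1 of 8 arrays ended the call of Ifit2, with an adjusted p of 0.052 to 0.077, and without knockout array 3 at 1 h 7 genes of the list were called. The itaconate-producing enzyme gene Acod1 (−2.47 ± 0.58) and the cannabinoid receptor gene Cnr2 (−2.43 ± 0.26) also had smaller responses. For sterol synthesis, 2 of 17 had a more negative response (5 adjusted over the list alone, 11 with the replicate block within genotype), with a median of −0.50. In camera the result was adjusted p = 0.0032 for it, and adjusted p = 0.73 with an estimated correlation. The sterol count was 1 without unstimulated array 1 of either genotype or knockout array 3 at 6 h, 5 without unstimulated knockout array 3 and 7 without knockout array 1 at 6 h. In limma, 2031 genes were called at 6 h, 599 (29.5%) with a higher and 1432 with a lower value in knockout cells. The higher share was 41.1% with quantile normalization repeated and 19.3% with arrays centred on their medians. The count was 4347 with the replicate block within genotype, with array weights 3268, with only the groups compared 1251, and without unstimulated knockout array 1 or 2 there were 1327 or 1284.

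At 1 h, limma called 0 genes for the interaction. An unadjusted p under 0.05 was found for 592 of 19938 genes, a smaller share than the 0.05 that chance gives. This fit leaves the pairing of arrays within a genotype in its error, which can make its p values too large. The low share therefore does not show that the responses were alike. With the replicate block within genotype, 0 genes were called too. Without knockout array 3 at 1 h, 1 gene was called, the immediate-early gene Fosb. In all arrays Fosb stood at 1.39 ± 0.31 log2 units and Ifnb1 at 2.52 ± 0.56 (SE, n = 3 per group, adjusted p = 0.9999 for both). The list of 24 immediate-early genes had a median of 0.26, with 4 genes called adjusted over the list alone (camera adjusted p = 1.6e-12, and adjusted p = 4.5e-04 with an estimated correlation). The NF-kB list had a median of 0.27 (camera adjusted p = 2.1e-09, and adjusted p = 0.38 with an estimated correlation). Over the 9 comparisons camera called 73 of 243 list results, and 14 held with an estimated correlation. These were the interferon-inducible list in the genotype comparisons without LPS and at 1 h, and immediate-early genes in the genotype comparison at 1 h, in both 1 h responses and in the 1 h interaction. The others were the NF-kB list in both responses of wild-type cells and in the 1 h response of knockout cells, inflammatory cytokines and mediators in all 4 LPS responses, and chemokines in the 1 h response of knockout cells.

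**Figure D3:**
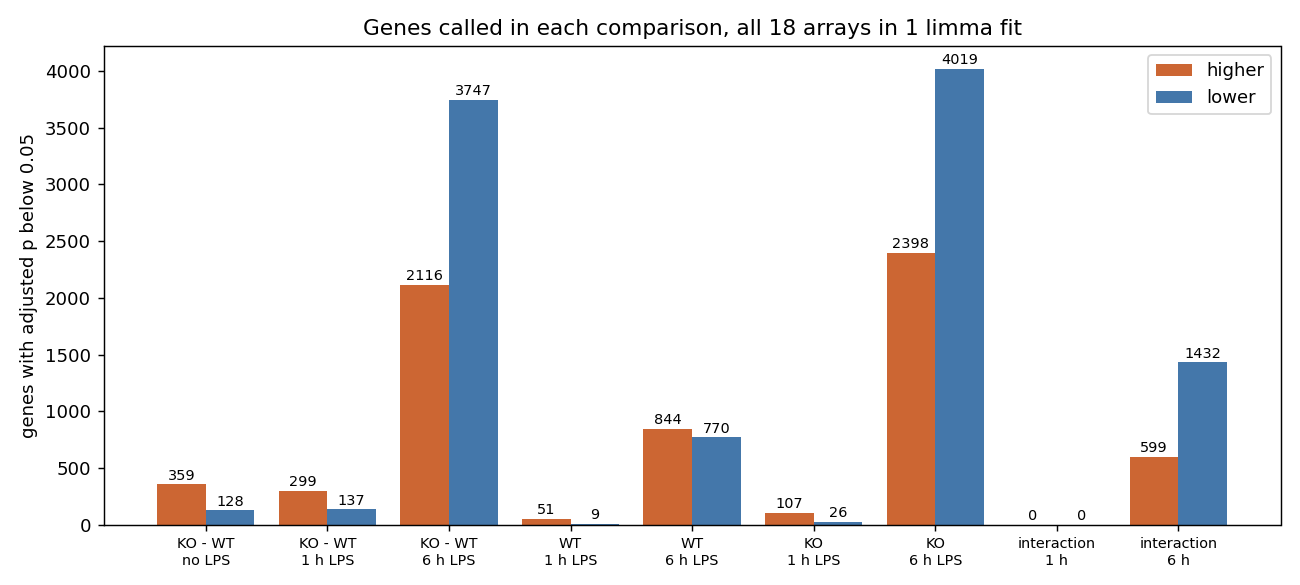
Number of genes called by limma at an adjusted p under 0.05 (vertical axis) with a higher (orange) or lower (blue) value in each of the 9 comparisons of the 18 arrays. The comparison of genotypes at 6 h had 2116 higher and 3747 lower genes, against 359 and 128 without LPS.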

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

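The tests of explanations in this part, and the splits of whole cultures for the interactions, were chosen only after the results were seen; the other splits were planned.

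The LPS response at 6 h differed between the genotypes for 2031 genes by the interaction test in limma, a difference between groups. Responses were larger in knockout cells for Ifnb1 (5.54 log2 units), Clic5 (4.54), Nos2 (4.14), Tnfsf10 (4.12), Cxcl11 (3.88), Dnase1l3 (3.42), U90926 (3.36), Il27 (3.31), Il6 (3.22), Cxcl9 (3.11), Hdc (2.85), Tlr3 (2.30), Il15 (2.29), Tcf4 (2.07), Cd40 (1.97), Cxcl1 (1.91), Socs1 (1.60) and Nfkbiz (1.38). They were smaller or more negative for Ifit3 (−3.94), Rtp4 (−3.74), Ifit1 (−3.47), Ifit2 (−2.67), Acod1 (−2.47), Cd300lb (−2.45), Cnr2 (−2.43), Hp (−2.31), Ankrd28 (−2.20), Tmem273 (−2.15), Scd2 (−1.78), Sesn1 (−1.68), Slc2a1 (−1.13), Lss (−1.07), Pparg (−1.02) and Mvd (−0.93). Among gene lists, the interaction at 6 h was called by camera for inflammatory cytokines and mediators (median 0.77), dendritic cell maturation (0.57), NF-kB genes (0.44), plasmacytoid dendritic cell markers (0.18), glycolysis and itaconate (−0.29) and sterol synthesis (−0.50). With an estimated correlation 0 of these 6 held: adjusted p = 0.34 for the inflammatory list and 0.73 for each of the other 5. At 1 h it was called for NF-kB genes (median 0.27), immediate-early genes (0.26), dendritic cell maturation (0.14) and inflammatory cytokines and mediators (0.06). With an estimated correlation the immediate-early list held (adjusted p = 4.5e-04), and the others had adjusted p = 0.38 (NF-kB) and 0.99 (maturation and inflammatory).

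Probe sets outside the gene test also carried genotype differences, a signal in data not used for the comparisons. Of 1621 probe sets with several symbols, limma called 30 without LPS, 36 at 1 h and 236 at 6 h. Of 12146 probe sets not listed in the annotation, it called 54, 40 and 811.

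Interferon-inducible genes were higher in unstimulated knockout cells. To test for endotoxin in these cultures, other LPS genes were examined: the 31 genes outside the list that LPS raised at least 2-fold in wild-type cells at both times had a median of 0.49, which is 20.9% of their wild-type response at 6 h (95% bootstrap interval 12.4 to 32.2%), against 142.6% for the interferon-inducible list. Endotoxin as the cause predicted at least 50%, and under 25% was set against it. The genes were picked with the same unstimulated wild-type arrays, which may raise the value, and the interval covers the choice of genes but not the spread between cultures, so a contribution of endotoxin stays open. A gap of 2.32 log2 units parted the lowest knockout and the highest wild-type array in the list's mean, but an exchange of all labels would leave the same gap, so wrong labels stay open, as does an effect of the Ubc9 loss itself.

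A total of 3747 genes were lower in knockout cells at 6 h, where these arrays also had lower 75th percentiles. With quantile normalization repeated, 76% of the genes called lower were still called lower (2847 genes), which argues against a narrower signal range as the whole cause of these calls. In all, 2898 were then lower and 2154 higher, against 3747 and 2116 before, so the excess of falls became smaller. Of 5 equal groups of genes by mean signal, groups 4 and 5, the brightest, held 1651 and 1442 of the falls. A narrower range as a part of the cause thus stays open. Without the 3 knockout arrays numbered 3, 77.7% were still called lower (2912 genes), which argues against these arrays as the whole cause. RNA integrity and cell death at 6 h are not given in the sources used here and stay open, beside an effect of the genotype.

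The 6 h response of Ifit1, Ifit2, Ifit3 and Rtp4 was smaller in knockout cells. The unstimulated knockout mean plus the wild-type response would be at least 14.74 for each of the 4 genes, above the highest value on any array, 13.71. Their knockout means at 6 h, 11.95, 12.07, 11.96 and 11.39, lie below that value. The 99th percentile of signal on these knockout arrays was 11.93 to 12.02. Means below the single highest value therefore do not exclude a limit near the top of the range. Whether the signal of these probe sets levels off at a lower value was not tested, so a limit of the signal and a smaller induction cannot be told apart. No biological explanation was tested.

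For the counts of genes called, the 6 arrays of each comparison make 10 splits, too few for a share under 0.05. Each real count was reached by 1 of the 10 splits, the real one. Every other split mixes arrays or cultures of both groups, so a difference between the groups, whatever its cause, widens the spread within them. Low counts in the other splits therefore decide nothing about the cause. The real counts were 487 without LPS, 436 at 1 h and 5863 at 6 h for the genotypes, 60 and 1614 for the 1 h and 6 h responses of wild-type cells, and 6417 for the 6 h response of knockout cells, and the highest other count was 0 in each. For the 1 h response of knockout cells it was 4, against 133. In the LPS comparisons numbers pair the arrays, and for the genotypes at 6 h they do so only by the rule given above. In these comparisons 4 splits part all 3 pairs, and the highest of the others among them called 0 genes. For the interactions, whole cultures were split. At 6 h the real count of 2031 was reached by 1 of 10 splits, with 0 as the highest other. At 1 h, 592 genes had an unadjusted p under 0.05 in limma, fewer than by chance, in the fit without pairing. There all 10 splits gave the real count, 0. An earlier form of this test relabelled arrays within each condition separately. There 8 of 100 relabellings, the real one included, gave at least 2031 genes at 6 h, and the highest other gave 4470. Its outcome decides nothing, because such a relabelling turns the genotype difference itself into an interaction.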

How the results depend on the processing

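The fit without the 3 knockout arrays numbered 3 and camera with blocks within genotype were tests chosen only after the data were seen. The counts of genes for the genotypes at 6 h (5863) and for the 6 h response of knockout cells (6417) stayed within 1.5 times under all alternatives, with 4118 to 6461 and 4702 to 6862 genes when 1 array was left out. For values outside 1.5 times the cause was not tested, except that fewer arrays give fewer degrees of freedom.

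With the replicate block over all arrays, which the check of the numbers did not bear out across genotypes without LPS and at 1 h, 924 genes were called for the genotypes without LPS (487 without the block) and 828 at 1 h (436). The random replicate block (correlation 0.27) called 120 and 2524 genes for the 1 h and 6 h responses of wild-type cells (60 and 1614), 284 for the 1 h response of knockout cells (133) and 3835 for the 6 h interaction (2031). The replicate block within genotype called 133, 3002, 309 and 4347 genes for these results. Array weights called 929 genes for the genotypes at 1 h, 281 for the 1 h response of knockout cells and 3268 for the 6 h interaction. With only the groups compared, 153 and 257 genes were called for the genotypes without LPS and at 1 h, 31 and 46 for the 1 h responses of wild-type and knockout cells, and 1251 for the 6 h interaction.

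Leaving out 1 array gave 274 (without unstimulated knockout array 3) to 536 genes for the genotypes without LPS, and 243 to 521 at 1 h. It gave 28 to 68 and 901 to 1752 for the 1 h and 6 h responses of wild-type cells, and 78 to 146 for the 1 h response of knockout cells. For the interactions it gave 0 to 1 at 1 h and 1284 to 2476 at 6 h. Without the knockout arrays numbered 3, 79 genes were called for the 1 h response of knockout cells and 1 for the 1 h interaction.

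Of 243 list results, camera called 73, and 14 with an estimated correlation. The rotation test fry called 71, of which 54 were shared. With the replicate block 82 were called, with 0 lost. With the replicate block within genotype 50 of 162 were called, against 43, with 0 lost and 7 gained. Those were the cell cycle (adjusted p = 5.1e-04) in the 6 h response of wild-type cells, neutrophil and granule markers (0.023) in that of knockout cells, and in the 6 h interaction the cell cycle (5.5e-06), chemokines (0.015), immediate-early genes (0.047), MHC and antigen presentation (0.047) and p53 targets (0.048). With an estimated correlation and no block these had adjusted p = 0.98, 0.47, 0.76, and 0.73 for the last 4. For the genotypes at 6 h the replicate block gained 2 list calls, p53 targets (0.028) and glycolysis and itaconate (0.037), both with adjusted p = 0.47 with an estimated correlation and no block. The blocks changed 0 calls of named genes. Among the 243 list results, without the knockout arrays numbered 3 there were 74, with 6 lost. The cell cycle list in the genotype comparison without LPS, lower with all arrays (adjusted p = 0.033, and adjusted p = 0.92 with an estimated correlation), reversed without the knockout arrays numbered 3 (adjusted p = 0.54). With no fold threshold the genotypes shared 46 rises and 4 falls at 1 h, and 531 rises and 598 falls at 6 h (36, 0, 196 and 67 at 2-fold). At a log2 change of 2 they shared 12 rises at 1 h, and 52 rises and 0 falls at 6 h.

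Of 350 values of named genes, 0 changed direction under any alternative run. Fits with only the groups compared lost 66 calls and gained 1, trend and robust variances lost 12, quantile normalization 8, median centring 4 and array weights 2. Leaving out 1 array lost 4 to 30.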

Other observations

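The test on sterol synthesis genes below was chosen only after the result was seen, and the test on late LPS genes was planned.

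Of 20 genes of the SUMO machinery 3 were higher in unstimulated knockout cells (6 adjusted over the list alone), with a median of 0.07 log2 units (camera adjusted p = 0.033, and adjusted p = 0.38 with an estimated correlation). At 6 h, 6 were higher and 6 lower (12 adjusted over the list alone), with a median of −0.07 and a mean of 0.17 (camera adjusted p = 0.75). Without LPS the medians were −0.15 for p53 targets (camera adjusted p = 0.83), −0.05 for the integrated stress and unfolded protein response (0.74), −0.13 for heat shock proteins (0.49) and 0.10 for glycolysis and itaconate (0.10). Of 21 p53 targets, 2 were higher and 9 lower at 6 h (11 adjusted over the list alone), with a median of −0.39 (camera adjusted p = 0.055; 0.028 with the replicate block; adjusted p = 0.47 with an estimated correlation and no block). Of 18 genes of the integrated stress and unfolded protein response, 2 were higher and 4 lower at 6 h (8 adjusted over the list alone; median −0.05, camera adjusted p = 0.38). Of 10 heat shock proteins, 1 was higher and 4 lower at 6 h (6 adjusted over the list alone; median −0.21, camera adjusted p = 0.094), and 3 were called without knockout array 3. Of 15 genes of glycolysis and itaconate, 1 was higher and 6 lower at 6 h (7 adjusted over the list alone; median −0.20, camera adjusted p = 0.053; 0.037 with the replicate block; adjusted p = 0.47 with an estimated correlation and no block). Their count was 4 without knockout array 1 or 2 or wild-type array 1 or 2, and 3 without wild-type array 3.

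Of 15 conventional dendritic cell markers, 1 was higher and 3 lower in knockout cells at 6 h (4 adjusted over the list alone; 1 higher and 6 lower with the replicate block; 2 called without wild-type array 2; median −0.09, camera adjusted p = 0.60). Of 17 neutrophil and granule markers, 3 were higher and 1 lower at 6 h (4 adjusted over the list alone; median 0.20, camera adjusted p = 0.18). Their count was 2 without knockout array 2 and 1 without knockout array 3 or wild-type array 1. Without LPS, 0 genes were called of the lists for germline genes (20 measured, median 0.01, camera adjusted p = 0.85), B cells (9, 0.01, 0.85), T and NK cells (12, 0.05, 0.62), mast cells and basophils (12, 0.04, 0.83), erythroid cells (9, 0.06, 0.85) and stromal cells (12, 0.00, 0.85). At 6 h, 2 germline genes were higher (1 adjusted over the list alone; 1 without array 3 of either genotype; median 0.11, camera adjusted p = 0.16). Of the mast cell and basophil markers 2 were higher (2 adjusted over the list alone; median 0.14, camera adjusted p = 0.15), or 1 without knockout array 2 or 3 or wild-type array 1 or 2. Of the erythroid markers 2 were higher (2 adjusted over the list alone; median 0.22, camera adjusted p = 0.15), or 0 without knockout array 3 and 1 without knockout array 2 or wild-type array 1, 2 or 3. Of the stromal markers 1 was higher (0 adjusted over the list alone; median 0.12, camera adjusted p = 0.60), or 0 without knockout array 3 or wild-type array 1, and 2 without knockout array 1 or knockout array 3 at 1 h. Of the B cell markers 1 was lower (1 adjusted over the list alone; median 0.04, camera adjusted p = 0.75). The T and NK cell markers had 0 called, with a median of 0.19 (camera adjusted p = 0.18).

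A hypothesis was that the interferon response lowers sterol synthesis genes in knockout cells. In wild-type cells at 6 h of LPS, where the interferon-inducible list had a median of 1.99, the sterol list had a median of 0.06 and 1 of 17 genes was lower. These values go against a fall of sterol genes within 6 h of LPS in wild-type cells. At 1 h, 0 of the 35 interferon-inducible genes were called in these cells. At 6 h the list's means on their arrays were 7.98, 8.83 and 9.16, mostly below those of the unstimulated knockout arrays given below. A slower effect, or one at higher levels of these genes, may thus be missed. In the 6 h response of knockout cells, 27 of 35 interferon-inducible genes rose and 10 of 17 sterol genes fell (median −0.66), which goes with it. On the unstimulated knockout arrays 1, 2 and 3 the interferon-inducible list's means were 8.86, 9.48 and 10.43 and those of the sterol list 8.37, 8.0 and 7.61. Other lists were graded over these arrays too, with 8.25, 7.89 and 6.75 for the cell cycle and 8.56, 8.85 and 9.6 for macrophage markers. On the knockout arrays at 6 h the interferon-inducible means were level (11.24, 11.29 and 11.27), while the sterol means fell (7.9, 7.2 and 6.86). The order of the arrays thus decides nothing. The hypothesis therefore stays open for knockout cells, and the effect of interferon alone was not measured.

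A further hypothesis was that the genes at least 2-fold higher in unstimulated knockout cells are those that wild-type cells raise between 1 h and 6 h of LPS. Of 179 such genes, 71 (39.7%) were called higher at 6 h than at 1 h in wild-type cells, against 5.4 by chance and 3% of all genes. The share lies between the 50% set as the lower bound for the hypothesis and the 25% set against it, so the test leaves it open. Of the 31 on the interferon-inducible list, 30 were among them, and of the other 148 genes 41 (27.7%).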
